A study of Homo sapiens with 2 samples.

How the data were processed

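RNA from 2 cultures of BT549, an established human triple-negative breast cancer cell line, was sequenced as 1 library each. One library is labelled miR1290 and the other mimicNC, and these labels alone put the libraries in their groups. The labels name total RNA, the TruSeq RNA Sample Prep Kit v2 and paired reads of 100 bases on an Illumina NextSeq instrument. How miR-1290 was brought into the cells, the dose, the time of harvest and the sequence of any control RNA are not given in the sources used here.

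The values are gene-level TPM, transcript abundances scaled to a fixed total, as deposited by the authors in 1 table of 60609 gene identifiers. Per the submitters' processing notes, FastQC 0.11.4, cutadapt 1.8.3, HISAT2 2.1.0 and StringTie 2.2.1 were used with the GRCh38 genome. The settings of these tools and the annotation release are not given in the sources used here. TPM scales every library to the same total and keeps no read depth, so the depth is unknown and no counting interval is given. TPM is also relative: a few abundant transcripts that differ between libraries shift the values of the rest. The named kit does not mark the strand, and the strand setting used in quantification is not given in the sources used here. Values of overlapping genes, antisense genes and near-identical copies are therefore uncertain.

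Identifiers were matched without their version to GENCODE release 44 (GRCh38), and 60340 of 60609 matched. Of all identifiers, 18565 had no symbol of their own and were left out of gene lists. Values of the 110 symbols shared by more than 1 identifier were summed. Genes with a symbol and a mean TPM of 1 or more were called measured. There were 12764 such genes, of which 11359 were protein-coding, and 980 identifiers above the same minimum had no symbol.

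For each gene the ratio was log2((TPM + 1) in miR1290 / (TPM + 1) in mimicNC). The pseudocount of 1 makes this ratio smaller than the plain TPM ratio for genes of low level. With 1 library per group there is no replicate spread, so no test was run and no difference has a replicate check. The text counts genes at or beyond 2-fold and gives levels in both libraries.

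Each of 36 gene lists was summarised by the median log2 ratio of its measured members. That median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, which happens for 5% of lists of genes drawn at random. Lists with fewer than 5 measured members have values only. These percentiles describe the 2 libraries, and genes are not replicates.

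Matches to positions 2 to 8 of miR-1290 (UGGAUUUUUGGAUCAGGGA) were searched in the 3′ UTR of 1 representative transcript per protein-coding gene. The 3′ UTR was annotated for 11330 of the measured protein-coding genes, and 29 were not searched. The 8mer is AAAATCCA, the 7mer-m8 AAAATCC, the 7mer-A1 AAATCCA and the 6mer AAATCC. The median of genes with a 7mer-m8 or 8mer was compared with genes without any 6mer. It was also placed among 10000 random lists matched on expression (10 bins) and 3′ UTR length (5 bins). The shift was ranked among all 105 arrangements of the same bases.

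The gene lists, thresholds, seed classes, alternatives and the rule for named genes were fixed before the data were examined. The rule takes genes with a symbol, no small RNA or pseudogene, and at least 10 TPM in 1 library. From these it names the 12 highest and 12 lowest log2 ratios, and the 8 lowest among genes with an 8mer. It adds up to 4 members with the largest absolute ratio per list, each measured gene of the list of reported miR-1290 targets, and 7 markers. Some members that the rule names are not reported here. Near copies and overlapping genes named beside these were added after their values were seen.

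The alternatives fixed with them were pseudocounts of 0.1 and 5, no filter, a mean TPM of 10 or more, and centring on the median gene. Others were protein-coding genes only, a single identifier per symbol, matching on transcript length or GC content, the mean in place of the median, and other definitions of the seed match. A protein-coding background, removal of the trend with transcript length and GC content over 10 groups of each, and the exclusion of genes with particular 3′ UTR motifs were chosen after seeing the data. For the closing section, the median of genes with a motif was also set against genes without it, drawn from the same bins, and the difference is called the excess. This definition replaced an earlier one after first results had been seen, because the earlier one recovered too little of a planted effect in simulated data. Bounds of the excess come from redrawing the genes without the motif, so they leave out the spread of the genes with it. Percentiles given beside an excess are among random lists drawn from all genes of the bins, with or without the motif. The scan of 7-base motifs in the 3′ UTR used the ratio left after a fit to 3′ UTR length, AU content and expression, for motifs in at least 200 genes. It was repeated in each of 2 random, disjoint sets of 5665 genes, and the top motif was measured in the other set.

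The list procedure was tested on simulated lists of 30 genes among the 12764. It called 5.5% of 200 lists apart with no shift and 98% with a shift of 0.3. In 5 simulations on 2106 of the 11330 genes, planted shifts of −0.05 and −0.1 were recovered as a mean excess of −0.061 and −0.0997, and no shift as 0.0058. The scan ranked the planted motif first in 5 of 5 simulations at either size. In all these simulations the ratios were first shuffled among genes of like expression, and for motifs also of like 3′ UTR length. Shuffling removes the signals of other motifs and of genes that vary together. The simulations therefore do not show how the procedures perform beside such signals. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.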

Results

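The series concerns miR-1290, a microRNA that fibroblasts of breast tumours can pass to cancer cells in exosomes, and the growth of triple-negative breast cancer cells. The 2 libraries of the BT549 line were compared. BT549 is a mesenchymal-like human breast cancer line that lacks the oestrogen receptor. One library is labelled miR1290 and the other mimicNC, so each group has n = 1 and no difference given here has a replicate check. The table held TPM values, from which the read depth is unknown. TPM was above 0 for 23412 identifiers in the miR1290 library and for 22713 in the mimicNC library.

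The line's markers were at similar levels in both libraries. VIM, the mesenchymal filament gene vimentin, was at 2819 TPM in the miR1290 library and 3156 in the mimicNC library. CDH1, which encodes E-cadherin, was at 0.082 and 0.124 TPM, and ESR1, the oestrogen receptor gene, at 0.008 and 0.01. ERBB2 was at 24.4 and 26.7 TPM. The precursor gene MIR1290 was listed at 0 in both libraries, but this assay does not measure mature microRNA, so that value does not check the labels. Transcripts of the mitochondrial genome took 18.1% of TPM in the miR1290 library and 19.9% in the mimicNC library, and the mitochondrial ribosomal RNAs among them 1.53% and 2.28%. Among markers of other cell types, 9 fibroblast genes were measured, 4 higher and 5 lower in the miR1290 library (median log2 ratio −0.02, percentile 38.6). Only 1 leukocyte marker (CD68, 20.1 and 46.8 TPM), 3 endothelial markers (ROBO4, ENG and EGFL7, median −0.16) and 0 erythroid markers were measured.

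The first comparison asked which genes differed most between the libraries. GDF15, LIF and FST had the lowest ratios and SLX1B, CENPS-CORT and RGS5 the highest. GDF15, a stress-induced secreted factor (chromosome 19, 18374731 to 18389176, GRCh38), was at 11.95 TPM in the miR1290 library and 102 in the mimicNC library, a log2 ratio of −2.99. The cytokine gene LIF (3.85 and 35.9 TPM, log2 −2.93) and the activin-binding protein gene FST (2.56 and 25.9 TPM, log2 −2.92) were about as far apart. Among the highest ratios were MDK, the growth factor midkine (chromosome 11, 46380756 to 46383837), at 227 and 60.5 TPM, log2 1.89, and RGS5, a regulator of G-protein signalling, at 13.2 and 1.84 TPM, log2 2.32.

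Of 12764 measured genes, 154 were 2-fold or more higher in the miR1290 library and 324 were 2-fold or more lower, while the median log2 ratio of all genes was 0.01. Other genes with low ratios were BMP6 (−2.46), the transcription factor ATF3 (−2.45), the chemokine CXCL8 (−2.42), IRAK2 of interleukin-1 receptor signalling (−2.42), the matricellular protein gene CCN3 (−2.28) and the long non-coding RNA LINC01050 (−2.47). AKR1C1 (6.23 and 46.8 TPM, −2.73) and MT1F (1.17 and 11.5 TPM, −2.53) belong to families of similar sequence, so their reads can be shared. The related AKR1C3 was also lower (−1.13), as was MT1X (−1.40), while MT1E was at 2.39 and 1.79 TPM. PHLDA1-AS1 (−2.67) overlaps PHLDA1 on the other strand, which was at 55.1 and 93.0 TPM (−0.74), and the strand of their reads is unknown.

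Other genes with high ratios were the long non-coding RNA OLMALINC (44.1 and 11.5 TPM, log2 1.85), the semaphorin gene SEMA3F (36.6 and 11.2 TPM, 1.63), the sterol synthesis enzyme gene MSMO1 (1.49) and the caveolin gene CAV2 (116 and 41.0 TPM, 1.48). MEX3A (1.44), CENPV (1.40), the neurotrophin receptor gene NTRK3 (1.35) and HES6 (1.34) followed. The highest ratio among genes with at least 10 TPM in 1 library was 2.90 for SLX1B. It came with a lower value of its near-identical copy SLX1A, and their summed TPM of 42.9 and 27.2 gave 0.64. The read-through gene CENPS-CORT (2.56) overlaps CENPS, and their sums of 68.0 and 33.9 TPM gave 0.98.

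Counts and the ratios of low-level genes depend on the settings. With a pseudocount of 5, the log2 ratios were −1.42 for MT1F, −1.50 for LINC01050, −1.51 for IRAK2, 1.41 for RGS5, 1.93 for SLX1B, 1.60 for CENPS-CORT and 0.87 for NTRK3. With a pseudocount of 5, 35 genes were 2-fold higher and 143 lower, and with a mean TPM of 10 or more, 57 and 182. With a pseudocount of 0.1 the counts were 302 and 485, and among protein-coding genes 96 and 272. The share of the higher genes among all those beyond 2-fold was 32.2% as first counted and 19.7% to 38.4% under these settings. Among genes with a mean TPM of 1 to 3, the central 95% of log2 ratios ran from −1.25 to 1.05, and above 100 TPM from −0.88 to 0.70.

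**Figure D1:**
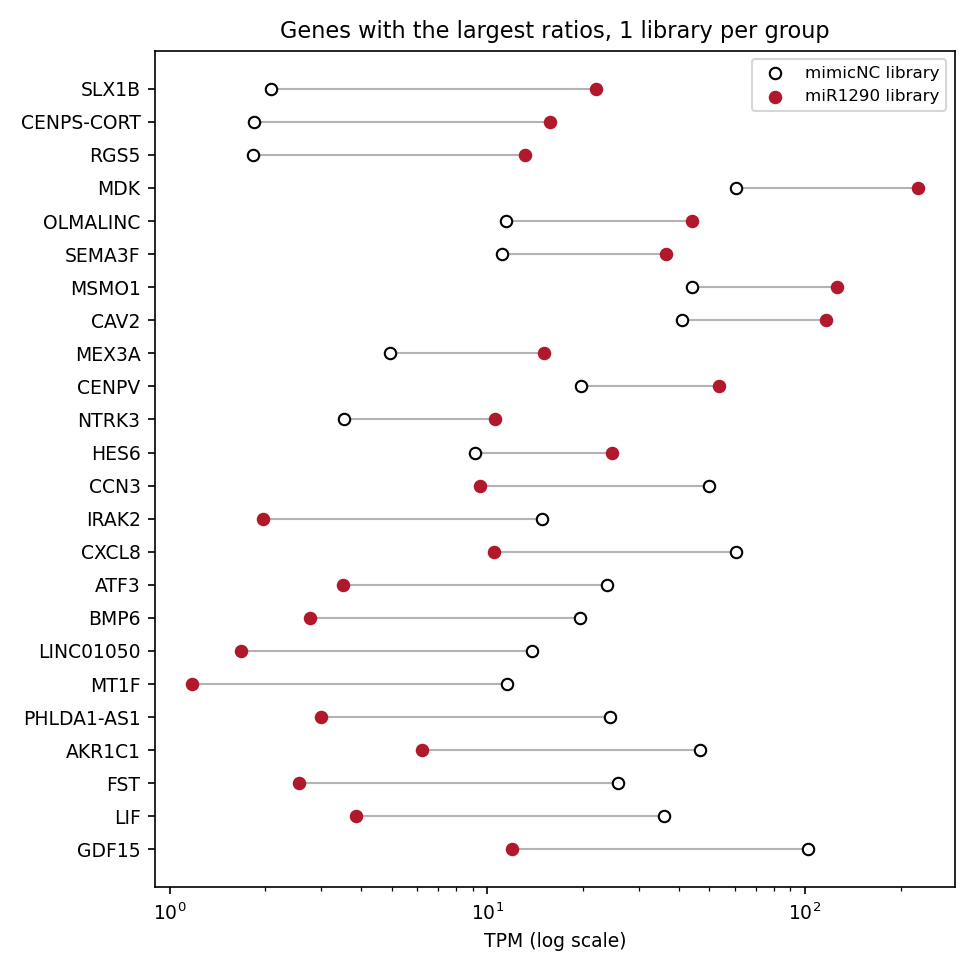
TPM on a log axis in the mimicNC library (open circles) and the miR1290 library (red circles), 1 library per group. Shown are the 12 highest and the 12 lowest log2 ratios among genes with at least 10 TPM in 1 library, without small RNAs and pseudogenes. GDF15, at the bottom, lies at 11.95 and 102 TPM, and MDK at 227 and 60.5 TPM.

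The next comparison asked how gene groups fixed before the data were examined differed, with proliferation as the process named in the study's title. Cell cycle genes were higher in the miR1290 library almost throughout. Of 43 S phase genes 40 were higher, with a median log2 ratio of 0.44 (percentile 100 of random lists), among them UNG (1.01), RAD51AP1 (0.94), the replication licensing inhibitor GMNN (0.91) and UHRF1 (0.86). Of 51 G2/M genes 50 were higher, with a median of 0.43 (percentile 100), among them NCAPD2 (0.95), CDC20 (0.91), TOP2A (0.83) and CCNB2 (0.81). MKI67, the gene of the proliferation marker Ki-67, was at 178 and 130 TPM (0.44). Only 1 gene of both lists, UNG, was 2-fold or more higher.

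Regulators of the G1 phase did not stand apart as groups by their medians. Of 13 G1 cyclin and E2F genes 10 were higher (median 0.21, percentile 96.7), led by SKP2 (0.92), E2F1 (0.45) and E2F2 (0.33). CCND1, the cyclin D1 gene, was at 93.2 and 94.3 TPM. In the list of CDK inhibitors and the Rb family the median was 0.09 (percentile 77.1) while the mean was −0.21, since CDKN1A (15.1 and 42.2 TPM, −1.42) and CDKN2B (37.4 and 101 TPM, −1.41) were lower and 7 of 12 members were higher. Of 22 p53 target genes 14 were lower (median −0.09, percentile 20.3), among them SESN2 (−2.09), BBC3 (−1.69) and PLK3 (−0.99). By the mean in place of the median, the G1 list (0.22, percentile 98.6) and the p53 list (−0.29, percentile 0.84) did stand apart.

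Genes of the cholesterol synthesis list were higher in the miR1290 library without exception. All 24 measured members had positive ratios, with a median of 0.71 (percentile 100), and 4 were 2-fold or more higher. Among these were MSMO1, HMGCS1 (344 and 148 TPM, 1.22) and MVD (1.05).

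The NF-kB, ATF4 and immediate early lists were lower in the miR1290 library. Of 16 measured NF-kB and inflammatory cytokine genes 14 were lower and 9 by 2-fold or more, with a median of −1.48 (percentile 0). With no filter the median of 24 genes was −0.81 (percentile 0). They included LIF, the apoptosis inhibitor gene BIRC3 (0.558 and 8.12 TPM, −2.55), CXCL8 and PTGS2 (−2.11), which encodes cyclooxygenase-2. Of 27 ATF4 and unfolded protein response genes 26 were lower and 13 by 2-fold or more (median −0.87, percentile 0). ATF3, the glutathione-degrading enzyme gene CHAC1 (−2.22), SESN2 (−2.09) and HERPUD1 (71.8 and 283 TPM, −1.96), of protein degradation at the endoplasmic reticulum, had the lowest ratios. Of 21 immediate early genes 16 were lower (median −0.36, percentile 0.04), among them FOS (−1.73), JUNB (30.6 and 103 TPM, −1.72) and ZFP36 (−1.52). ATF3 is counted in this list as well, and the mean of the list was −0.57.

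Of 23 lysosome and autophagy genes 20 were lower and 8 by 2-fold or more (median −0.83, percentile 0). The autophagy receptor gene SQSTM1 was at 296 and 875 TPM (−1.56), GABARAPL1 at 6.38 and 20.8 TPM (−1.56), and MAP1LC3B (−1.19) was lower as well. Of 17 NRF2 target genes 16 were lower (median −0.60, percentile 0), with HMOX1, the haem oxygenase gene, at 138 and 383 TPM (−1.46) and the cystine transporter gene SLC7A11 at 7.77 and 22.9 TPM (−1.44). Of 22 interferon-stimulated genes 17 were lower (median −0.54, percentile 0), among them the RNA sensor gene IFIH1 (−1.18), PARP14 (−1.11), IFI35 (−1.04) and IFIT3 (−0.79). That median was −0.15 over 38 genes with no filter (percentile 0.24) and −0.28 with a pseudocount of 5 (percentile 0.01). Of 4 measured metallothionein genes 3 were lower, too few for a percentile.

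Ribosomal protein genes and nuclear-encoded respiratory genes were slightly higher in the miR1290 library, and mitochondrially encoded genes slightly lower. Of 78 cytosolic ribosomal protein genes 74 were higher (median 0.22, percentile 99.9), RPS26 (0.45) and RPL35A (0.42) most, where random lists of equal expression had a median of 0.11. Of 71 nuclear-encoded oxidative phosphorylation genes 57 were higher (median 0.16, percentile 98.8), NDUFA9 (0.46) and SDHD (0.45) most, where random lists had a median of 0.07. Matching on transcript length put this list inside the bounds (percentile 96.2). Of 13 mitochondrially encoded genes 9 were lower (median −0.11, percentile 2.21), among them MT-CO2 (−0.30), but 5 of 11 alternative settings put this list inside the bounds, such as matching on GC content (percentile 3.85). Ribosome biogenesis (24 of 30 higher, median 0.16, percentile 97.6) and heat shock proteins (10 of 13 higher, median 0.26, percentile 97.6) lay just past the upper bound, and several alternative settings put each inside it. HSP90AA1 was at 2960 and 1347 TPM (1.14).

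Some groups that stood apart held members far apart in both directions. TGF-beta and YAP targets had a median of 0.27 (12 of 20 higher, percentile 99.7), with AXL, a receptor tyrosine kinase gene, at 77.6 and 33.3 TPM (1.20) and INHBA at 0.784 and 3.02 TPM (−1.17). With no filter on low values this median was 0.03 (percentile 51.3). Mesenchymal factors had a median of −0.16 (13 of 21 lower, percentile 2.37), with the collagen cross-linking enzyme gene LOX at 47.3 and 159 TPM (−1.73) and SERPINE2 at 202 and 529 TPM (−1.39), while AXL, also in this list, was higher. Of 11 alternative settings 6 put this list inside the bounds, such as matching on transcript length (percentile 4.33). Hypoxia and glycolysis genes had a median of −0.17 (17 of 28 lower, percentile 0.68), among them BNIP3L (−1.39) and NDRG1 (−1.14), but at a mean TPM of 10 or more the median was −0.06 (percentile 8.62). Of 20 measured replication-dependent histone genes 14 were lower (median −0.47, percentile 0), such as H2BC21 (−1.60), while H2AC14 (1.18) was higher. Most such histone transcripts lack a poly(A) tail, so their values depend on how RNA was selected, and with no filter the median of 40 genes was −0.04 (percentile 21.4), and with a pseudocount of 5 that of the 20 was −0.26.

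In total 18 of the 32 lists with a percentile stood apart, 8 higher and 10 lower, where lists of genes drawn at random would give 1.6. Genes of a preset list can vary together, and some lists share members. The 1.6 is therefore not the number to expect between any 2 cultures. Of these, 10 stood apart under all 11 alternative settings: S phase, G2/M, cholesterol and ribosomal protein genes higher, and the NF-kB, ATF4, immediate early, lysosome, NRF2 and interferon lists lower. Centring, 1 of the 11 settings, moves every gene equally and so is no check of a list. The other 8 lists came inside the bounds under at least 1 setting. Those within the bounds included pro-apoptotic genes (8 of 15 lower, percentile 51.4), anti-apoptotic genes (median −0.16, percentile 11.7), PI3K-AKT brakes (11 of 14 lower, median −0.15, percentile 10.1), small RNA silencing genes (median 0.14, percentile 91.8; 0.22 and percentile 97.6 at a mean TPM of 10 or more) and epithelial genes (7 measured, median −0.18, percentile 14.7). Collagens and matrix (percentile 40.3) had a median of −0.02 and a mean of 0.01. Wnt and Notch targets (percentile 77.1) had a median of 0.09 and a mean of −0.12, with HEY1 (−1.86) and HES4 (−1.44) lower. Breast subtype markers had a median of −0.13 (percentile 15.2), with XBP1 (−1.58) lower and GATA3 (0.90) higher. The 15 housekeeping genes had a median of 0.02 and a mean of −0.05 (percentile 27.7).

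**Figure D2:**
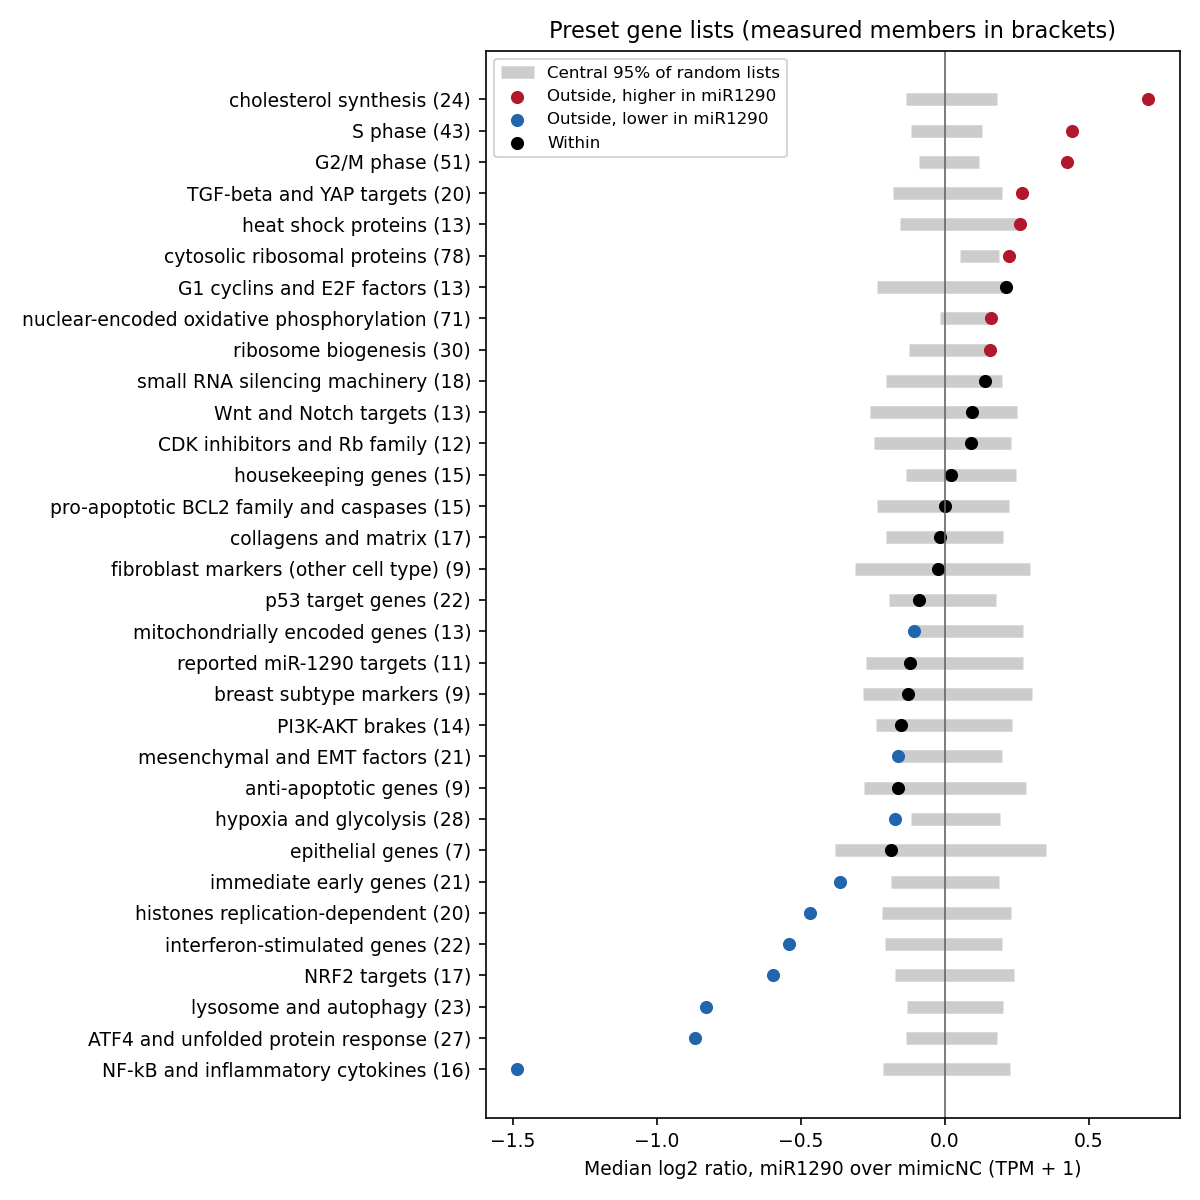
Median log2 ratio of miR1290 over mimicNC (TPM + 1) for each of the 32 lists with 5 or more measured members (points), with the central 95% of 10000 expression-matched random lists (grey bars). Cholesterol synthesis has the highest median, 0.71, and NF-kB and inflammatory cytokines the lowest, −1.48, both outside their grey bars.

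The last comparison asked whether transcripts that miR-1290 could pair with were lower in the miR1290 library. Genes with a seed match in the 3′ UTR were slightly lower as a class, and genes with the longest match more so. The 1868 genes with a 7mer-m8 or 8mer had a median log2 ratio of −0.07, against 0.03 for 7375 genes without a 6mer, a shift of −0.10. The shift was −0.05 with no filter, and −0.05 after removal of the trend with transcript length and GC content. Of the former 57.6% had a negative ratio and of the latter 47.1%. The median of the genes with a match lay below all medians of random lists of the same expression and 3′ UTR length, whose central 95% ran from −0.05 to −0.01. Genes with a match had longer 3′ UTRs, 3266 against 820 bases at the median, and the median of the length-matched random lists was −0.03.

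By class, the shift was −0.14 for 773 genes with an 8mer (percentile 0), −0.07 for 1095 with a 7mer-m8 only (percentile 6.18), −0.09 for 851 with a 7mer-A1 only (percentile 0.345) and −0.05 for 1236 with a 6mer only (percentile 59.5). The 7mer-m8 and 6mer classes were thus within the range of random lists. Among all 105 arrangements of the bases of AAAATCC, the seed match had the 2nd lowest shift, behind the 7mer-A1 AAATCCA (−0.11). Of the other arrangements, the lowest shift was −0.08 and the median −0.05.

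Genes with an 8mer and the lowest ratios were named with the position of the match, each in the 3′ UTR of an exon of the representative transcript. ATF3 has its AAAATCCA at chromosome 1, 212620256 to 212620263 (GRCh38, plus strand), and IRAK2 at chromosome 3, 10242420 to 10242427 (plus strand). WBP2 (16.2 and 71.4 TPM, −2.07) has it at chromosome 17, 75845784 to 75845791 (minus strand). PAX8, a transcription factor gene (8.05 and 36.9 TPM, −2.07), has it at chromosome 2, 113216283 to 113216290 (minus strand). HSPA5, the endoplasmic reticulum chaperone gene (366 and 903 TPM, −1.30), has it at chromosome 9, 125235481 to 125235488 (minus strand). CPEB2 (−1.68), CCDC186 (−1.39) and OSTC (41.8 and 108 TPM, −1.35) complete the 8. ATF3 and HSPA5 also belong to the ATF4 and unfolded protein response list, of which nearly all members were lower.

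Genes reported elsewhere as miR-1290 targets did not stand apart as a list. Of 11 measured, 8 were lower and 3 higher, none by 2-fold (median −0.12, percentile 16.7). The lower ones were KIF13B (−0.78), NAT1 (−0.76), GSK3B (−0.62), IRF2 (−0.60), CHUK (−0.34), INPP4B (−0.12), PPP4R3A (−0.09) and SOCS4 (−0.07). BCL2 (0.22), SCAI (0.24) and NFIX (0.31) were higher. Of the 6 with an 8mer, 4 were lower (KIF13B, CHUK, PPP4R3A and SOCS4) and 2 higher (BCL2 and SCAI). This list was compiled from general knowledge and is not a full catalogue.

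**Figure D3:**
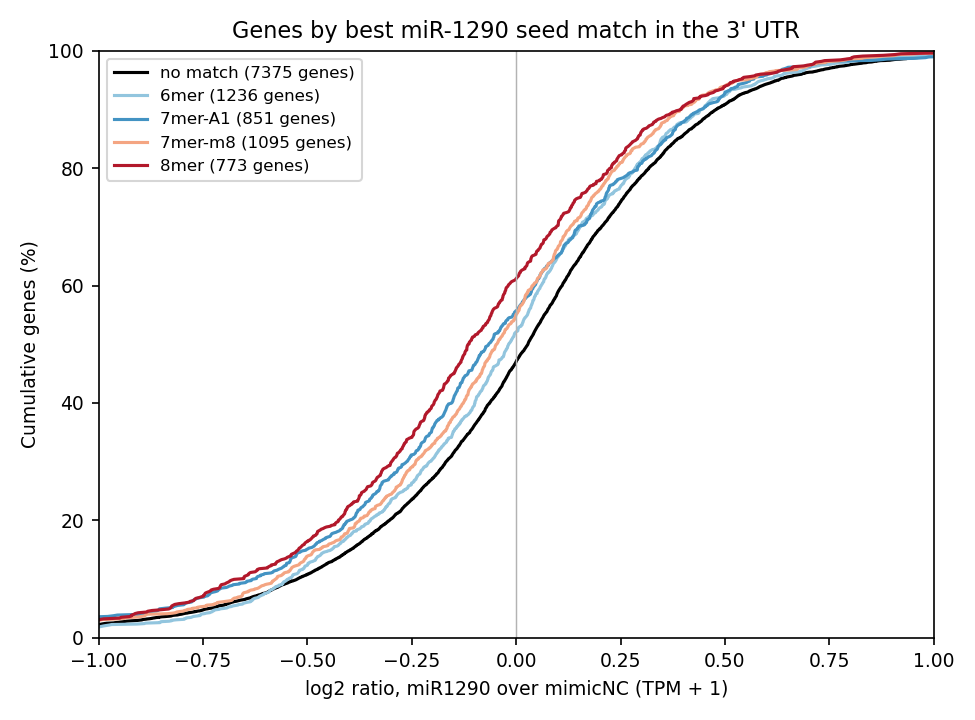
Cumulative percentage of protein-coding genes against the log2 ratio of miR1290 over mimicNC (TPM + 1), by the longest miR-1290 seed match in the 3′ UTR. The curve of the 773 genes with an 8mer lies, over most of the range, to the left of the curve of the 7375 genes without a match, with medians of −0.11 and 0.03.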

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

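The protein-coding background, the removed length and GC trend and the exclusion of genes with 3′ UTR motifs were chosen after seeing the data. Of the 18 lists apart, 10 stayed apart the same way under all 11 other settings, and the seed shift stayed negative, from −0.05 to −0.14, with percentiles of 0.56 or lower. The calls below ended. The cause was not tested except where fewer genes entered, and for centring it follows from the setting itself. A pseudocount of 0.1 gave medians of 0.264 for heat shock, 0.160 for ribosome biogenesis and −0.163 for mesenchymal factors, with 302 genes 2-fold higher. A pseudocount of 5 gave 35 higher and 143 lower. With no filter, which admits genes near 0, the medians were 0.239 for heat shock, −0.0690 for hypoxia, −0.106 for mitochondrially encoded genes, 0.158 for ribosome biogenesis, 0.0287 for TGF-beta and YAP targets and −0.0391 for histones. A mean TPM of 10 or more left fewer genes and gave −0.0612 for hypoxia, 0.149 for ribosome biogenesis, and 57 higher and 182 lower genes. Protein-coding genes alone, again fewer, gave 96 higher. Centring gave 0.258 for heat shock. It moves every gene by the same amount, so only the random draw of lists can have ended that call. Matching on transcript length left the medians of oxidative phosphorylation (0.159), ribosome biogenesis (0.158) and mesenchymal factors (−0.163) inside the bounds. Matching on GC did so for mitochondrially encoded genes (−0.106) and mesenchymal factors (−0.163), and the protein-coding background for these and ribosome biogenesis (0.158). Means were −0.0863 for mitochondrially encoded genes, 0.119 for ribosome biogenesis and −0.192 for mesenchymal factors. With the trend removed, heat shock was at 0.202 and oxidative phosphorylation at 0.0955. Without genes carrying AAATCC or AGTACA, fewer members remained, with −0.0424 for hypoxia, 0.157 for oxidative phosphorylation, 0.171 for ribosome biogenesis and −0.211 for mesenchymal factors. In that setting the mitochondrially encoded list kept its median of −0.106 and came inside the bounds of random lists drawn from the remaining genes. Calls were gained for p53 targets (−0.364) and PI3K-AKT brakes (−0.331) without genes carrying either motif, for small RNA silencing genes (0.225) at a mean TPM of 10 or more, and by the mean for the G1 list (0.223) and p53 targets (−0.292). Some lists kept their call while the value moved by over 1.5 times: the interferon list was at −0.151 and the NF-kB list at −0.809 with no filter, mesenchymal factors at −0.256 at a mean TPM of 10 or more, and, with the trend removed, mitochondrially encoded genes at −0.217 and ribosomal protein genes at 0.144. TGF-beta and YAP targets were at 0.517 over the 6 members without either motif. Fewer than 5 members, and so no value, were left for histones and epithelial genes at a mean TPM of 10 or more, and for anti-apoptotic genes, epithelial genes and reported targets without either motif. No paired analysis was possible because each group has 1 library. The depth behind the TPM values is unknown, so the precision of low values is too.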

Other observations

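The test of 3′ UTR length and base composition for AGTACAA, the excess as a measure, the test on 9 selected lists, the settings without AGTACA and with the trend removed, and the motif scan were chosen only after the result was seen. Matching the seed genes on AU content was fixed earlier, but its use as a test of that explanation was written afterwards. The tests on split sets of genes were added last, after the same values over all genes had been seen. The 7-base and 8-base site test and the test of a known control sequence were chosen after the scan but before their own results were seen. The reading of the control sequence test as undecided, against the bound written for it, was set after its value was seen.

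Genes that share a short 3′ UTR motif were higher in the miR1290 library. In a scan of 13880 motifs of 7 bases in 3′ UTRs, the highest standardised value of the corrected mean ratio belonged to AGTACAA (1103 genes, 8.39), followed by TAGTACA (878 genes, 5.11). The GC-rich motifs CGCCTGT (5.08), GGAGGCC (4.98) and GGCCGAG (4.92), which do not resemble TAGTACA, were almost level with it. GGAGGCC and GGCCGAG overlap in GGCC, so they need not be separate signals. AGTACAA and TAGTACA lie within TAGTACAA, carried by 247 genes with a median log2 ratio of 0.10. Among these genes CAV2 was at 116 TPM in the miR1290 library and 41.0 in the mimicNC library (1.48), GLO1, which detoxifies methylglyoxal, at 140 and 54.8 (1.33), and RAVER2 (0.98), NR1D2 (0.97), GALNT1 (0.96) and RAD51AP1 (0.94), which is also in the S phase list, followed. These genes were picked by their ratios after the scan. At the other end of the scan the lowest standardised value was that of AAATCCA, the 7mer-A1 match of miR-1290 (−5.59), and its 7mer-m8 match AAAATCC was 4th (−4.27). Between them lay the AU-rich motifs TATTTAT (−5.20) and ATTTATT (−4.50).

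The identifier ENSG00000112096.18, which had no symbol in the annotation used here, was at 151 TPM in the miR1290 library and 739 in the mimicNC library (log2 −2.29).

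Genes with a miR-1290 seed match were lower in the miR1290 library. Against genes without a match in the same bins of expression, 3′ UTR length and AU content, the excess median was −0.0525 (percentile 0), so length and base composition do not account for the whole of it. With bins of expression and 3′ UTR length only, the excess was −0.0640. In such bins it was −0.0545 (percentile 0) after the trend with transcript length and GC was removed. Without genes carrying AGTACA, which left 900 seed-match genes, it was −0.0464 (percentile 0.56) in such bins. A candidate explanation is repression of some of these transcripts by miR-1290 in the miR1290 library. The excess is small, and with 1 library per group the hypothesis was not tested in a repeat. Over genes without a match, in bins of expression and 3′ UTR length, the 7mer-m8 class alone had an excess of −0.0441. Redrawing only the genes without a match gave bounds of −0.0721 to −0.0159. Among random lists drawn from all genes, with or without a match, the class was within the range (percentile 6.18).

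Genes with AGTACAA or TAGTACA were higher in the miR1290 library, and since the motifs were picked on these ratios, the scan was repeated in each of 2 random, disjoint sets of 5665 genes: AGTACAA came first in both, and its genes in the other set had an excess median of at least 0.127 matched on expression, 3′ UTR length and AU content, and at least 0.119 after removal of the transcript length and GC trend (percentile 100 in each), which argues against those trends as the whole cause. In the same held-out sets, genes with AGTACAA in the coding sequence and no AGTACA in the 3′ UTR had an excess of at most 0.0249. They were not apart from random lists (percentiles 73.9 and 65.6). Their excess also lay below floors of 0.109 and 0.112, the criterion written for this test. Those floors came from draws of 485 of the 559 and 478 of the 544 3′ UTR genes. Such draws are nearly the whole set, so the floors hold little of its spread and decide nothing by themselves. Upper bounds of 0.0637 and 0.0652 lay below lower bounds of 0.0979 and 0.0992 for the 3′ UTR genes. Those bounds redraw only genes without the motif and leave out the spread of the genes with it, so they are no confidence intervals. The percentiles, but not the floors or bounds, argue against a property of the genes wherever they carry the motif as the whole cause. A silencing RNA in the mimicNC library, with a seed that pairs with the motif, may account for the pattern but stays untested: the median was higher by 0.0667 in 8-base than in 7-base genes, and by 0.0549 in 7-base than in 6-base genes, yet the motifs were picked on these same ratios, so this order speaks neither for nor against it. The C. elegans microRNA miR-239b-5p (UUUGUACUACACAAAAGUACUG), a sequence known from its use as a control, pairs with AGTACAA through positions 2 to 8, but the prediction made for it was not met: genes with its 8mer AGTACAAA differed by −0.0035 from genes with AGTACAA alone, which meets the bound set beforehand for rejecting it, and 833 genes with its 7mer-A1 alone were not apart (percentile 10.9). That difference was well within random draws (percentile 39.2), so it does not exclude this sequence, the sequence of the control is not given in the sources used here, and a ratio of 2 libraries cannot tell a lower level in one from a higher level in the other.

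Cell cycle and cholesterol lists were higher and the stress lists other than heat shock proteins lower in the miR1290 library, and after removal of the transcript length and GC trend 16 of 18 lists were still apart, which argues against that trend as the whole cause. Without genes carrying AAATCC or AGTACA in the 3′ UTR, 13 of 18 lists were still apart. That is just under the share set beforehand for excluding direct repression through seed matches in either library. Of the lists that lost their call, only hypoxia had a much smaller median (−0.17 before and −0.04 after). The oxidative phosphorylation, mitochondrially encoded, ribosome biogenesis and mesenchymal medians stayed about as large or grew, so those lost calls do not speak for direct repression. By the count of lists, that explanation stays undecided for the 18. Only after this was seen were the S phase, G2/M, cholesterol, ATF4, NF-kB, NRF2, lysosome, immediate early and interferon lists looked at alone. They were chosen because they stood far apart, when it was already known that each kept its call in this setting. That all 9 of 9 were still apart is therefore no test of direct repression. The values show only that members without such a site still differed, with medians such as 0.43 for S phase and −0.72 for ATF4 genes. Direct repression of these members through sites in the searched 3′ UTR cannot account for those medians, since they lack such sites. Effects that pass through another regulator, on either side of the comparison, remain open. Culture density, nutrients or handling that differed between the 2 cultures could also give such lists, and with 1 library per group this cannot be told apart from an effect of miR-1290.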
